A study of Mus musculus with 2 samples.

How the data were processed

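The data are 2 single-cell RNA libraries, replicate 1 and replicate 2, of brain cells from male mice aged 4 to 6 weeks. The mice carried a Cre recombinase driven by Dmp1 sequences and a Cre-dependent reporter that places the green fluorescent protein Dendra2 in mitochondria. Cells with Dendra2 signal were sorted by flow cytometry, so both libraries belong to 1 group. Per the labels, they were made with a 10x Genomics 3' v3.1 kit, in which each captured transcript carries a unique molecular identifier (UMI).

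The deposited matrices hold whole-number UMI counts per gene and barcode, made with Cell Ranger 3.1.0 per the file headers. The submitters' processing notes also name CASAVA 1.8 and Seurat 2.3.4, with no role given. The genome build is not given in the sources used here. Of the 30905 gene identifiers in the matrices, 30766 are in GENCODE release M21 (GRCm38), from which the position of Dmp1 was taken. No cell annotation was used here, and no unsorted or Dendra2-negative cells and no reporter or Cre transcript were analysed here.

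Barcodes were kept with at least 500 genes, at least 1000 UMIs and under 20% of UMIs from mitochondrially encoded genes. Doublets were scored per library with Scrublet in scanpy 1.11.5 at an expected rate of 6%. Scrublet called 194 of 8041 barcodes (2.41%) in replicate 1 and 2 of 6498 (0.0308%) in replicate 2, where it has not worked, so doublets remain in replicate 2. As an added alternative, the highest 6% of doublet scores of each library were left out. After the filters 7509 and 6425 barcodes were kept, called cells here, with medians of 6810 and 3016 UMIs. Both libraries were scaled to 10000 counts per cell and log-transformed, and clustered together with no batch correction on 2000 variable genes chosen across the libraries, 30 principal components, 15 neighbours and Leiden resolution 1 (igraph 0.11.9). Every gene of the fixed lists was kept out of the variable genes, so neither Dmp1 nor the mitochondrial lists shaped the clusters.

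Clusters were named "-like" from markers of 23 cell classes. A marker counted for a cluster at 50 CPM (a gene's UMIs as a scaled share of all UMIs) or more and within 4-fold of its highest cluster. A class needed at least 3 such markers, a share of at least 0.5 of its markers and a lead of 0.25 over the next class, and no other class could have more markers among the 10 leading genes (detected in a share of at least 0.25 of the cells). A cluster with a median under 1/3 of its library's median UMIs and no own marker among those genes also stayed unnamed. This scoring rule was set after the clusters were seen. It left 5 of 22 clusters unnamed, with 1113 cells, 6.94% of replicate 1 and 9.21% of replicate 2. Immediate-early and heat-shock genes led pericyte-like cluster 12 and smooth muscle-like cluster 13, nearly all of whose cells came from replicate 2. Different clusters held the smooth muscle-like cells of the libraries, clusters 2, 4 and 5 in replicate 1 and clusters 13 and 2 in replicate 2. Likewise, most pericyte-like cells were in clusters 0, 1 and 6 in replicate 1 and in clusters 8 and 12 in replicate 2.

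The markers, 27 gene lists (573 genes), the filters, the clustering settings, the tests and most alternatives were chosen before the data were examined. The tests then planned compared astrocyte-like cells with endothelial-like cells and with the other classes, and astrocyte-like cells with and without a Dmp1 UMI. They required 30 astrocyte-like cells in each library, and 20 with a Dmp1 UMI. The libraries had 37 and 2 astrocyte-like cells, 3 and 0 of them with a Dmp1 UMI, so none of these tests was run. Replicate 1 alone gave endothelial-like and astrocyte-like values with no test: per list, the median log2 ratio of CPM with 10 CPM added, over genes with a mean of at least 20 CPM, and its percentile among 10000 random lists matched on mean expression.

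In place of the planned tests, after the data were seen, the same design was applied to 4 classes with at least 30 cells in each library: smooth muscle-like, pericyte-like, endothelial-like and oligodendrocyte-like. Raw counts were summed per class and library into 8 sums. They were fitted with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr) with library as a block, which left 3 residual degrees of freedom. The block was planned because all classes of a library came from the same sorted preparation. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Standard errors (SE) are the log2 fold change divided by the square root of its F statistic. Since the classes were built from expression, calls were counted only over genes that were neither clustering features nor markers. Gene lists were tested with limma 3.58.1 camera at a preset correlation of 0.01, again with an estimated correlation, and with fry.

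A further test compared smooth muscle-like cells with a Dmp1 UMI to 3 cells each without one, of the same library and class and nearest in total UMIs. It used the same edgeR test on 4 sums, with Dmp1 left out and library as a block. Only 1 residual degree of freedom remains there, so the spread is taken almost wholly from the trend over all genes. The p-values and SE of the matched test therefore do not measure how far the libraries differ in each gene. The labels do not say that the replicates are separate animals, so p-values of the class tests measure only the spread between these libraries, which may be technical.

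Shares of cells have exact binomial (Clopper-Pearson) and CPM values exact Poisson 95% intervals, and a count of 0 was bounded at 3 counts. Intervals and bounds cover counting error only. To compare cells of different depth, the expected share of cells with a Dmp1 UMI was also computed after thinning each cell to 2000 UMIs, leaving out shallower cells. Log2 ratios within a single library had 1 CPM added.

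Genes were named by a rule. It took Dmp1, the 4 members with the smallest adjusted p of each list whose call passed, and outside the lists the 10 largest fold changes in each direction. The latter needed an adjusted p under 0.05, the same sign in both libraries and at least 50 CPM in the higher class of both, on the TMM scale of edgeR, whereas CPM values in the text use all UMIs without TMM. Some genes that met the rule are not reported here. Genes outside the rule are said to be chosen after their values were seen. Between the libraries, the 5 largest ratios each way within a class were named, with at least 100 CPM in the higher library.

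Alternatives were no mitochondrial filter, doublets kept, a 2000 UMI minimum, Leiden resolutions 0.5 and 2, fixed lists allowed among the features, each library clustered alone, DESeq2 1.42.0 (its test, or its size factors in edgeR), no expression filter, no replicate block, 100 cells per class, only the compared classes in the fit, each replicate alone, and for the matched test 1 matched cell or matching within the cluster. All those of the substituted tests were added after the data were seen.

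The tests were run first on simulated counts with 200 changed genes. For endothelial-like against smooth muscle-like cells (12421 genes) they recovered 10.5% of 1.5-fold, 59.2% of 2-fold and 100% of 4-fold changes with 4 false calls. For smooth muscle-like cells against the other classes (12411 genes) the shares were 21.1%, 80.6% and 100% with 7 false calls. For the matched test (10112 genes) they were 47.1%, 89.9% and 100% with 7 false calls. In each simulation the changed list was called and 0 of 20 unchanged lists were. The simulated genes varied independently, while the correlation estimated in the data reached 0.70 for complex V in endothelial-like against smooth muscle-like cells. These runs therefore do not show how often camera at the preset correlation calls lists of correlated genes falsely. Each gene was also simulated with the spread of the trend over all genes, which is what the matched test assumes. The false calls counted, above all for the matched test, thus do not show how often genes with a wider spread are called falsely.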

Results

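Dendra2-sorted brain cells were profiled to ask which cell types carried the mitochondrial reporter driven by Dmp1-Cre. Dmp1 (dentin matrix protein 1) encodes a secreted phosphoprotein best known from bone and dentin. In such mice, a cell can carry Dendra2 because it or its precursor expressed Cre, or by taking up mitochondria from another cell, which the series title names as its subject. Replicate 1 held 8236 barcodes with 59026190 UMIs (median 6630 per barcode), and replicate 2 held 7077 barcodes with 26218090 UMIs (median 2852). The sort selected for Dendra2, so all shares are shares of sorted cells. All means over libraries have n = 2.

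Mural cells of blood vessels made up most of the sorted cells. Smooth muscle-like and pericyte-like cells together were 83.2% of replicate 1 and 65.3% of replicate 2 (74.3% ± 12.7, SD, n = 2). Smooth muscle-like cells, named from contractile genes such as Acta2, Tagln and Myh11, were 48.1% (95% interval 46.9 to 49.2) of replicate 1 and 18.8% (17.9 to 19.8) of replicate 2. Pericyte-like cells, named from markers such as Kcnj8, Abcc9 and Vtn, were 35.1% (34.1 to 36.2) and 46.5% (45.3 to 47.7). Endothelial-like cells were 3.33% (2.94 to 3.76) and 17.6% (16.7 to 18.6), and oligodendrocyte-like cells 1.05% (0.834 to 1.31) and 6.60% (6.00 to 7.23).

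Astrocyte-like cells were 37 of 7509 cells (0.493%, 0.347 to 0.679) in replicate 1 and 2 of 6425 (0.0311%, 0.00377 to 0.112) in replicate 2. Committed oligodendrocyte precursor-like cells were 2.84% and 0.405%, border macrophage-like cells 1.03% and 0.0778%, microglia-like cells 0.426% and 0.202%, and vascular fibroblast-like cells 0.173% and 0.545%. Choroid plexus epithelium-like cells were 0.506% of replicate 1, while replicate 2 had none among 6425 cells, which allows a share of up to 0.0467%. The intervals of the libraries did not overlap in any class named here except the microglia-like cells (0.292 to 0.601 and 0.108 to 0.346). The spread between the libraries was near the mean itself for endothelial-like (10.5% ± 10.1) and oligodendrocyte-like cells (3.83% ± 3.92), and smaller for smooth muscle-like (33.4% ± 20.7) and pericyte-like cells (40.8% ± 8.03).

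**Figure D1:**
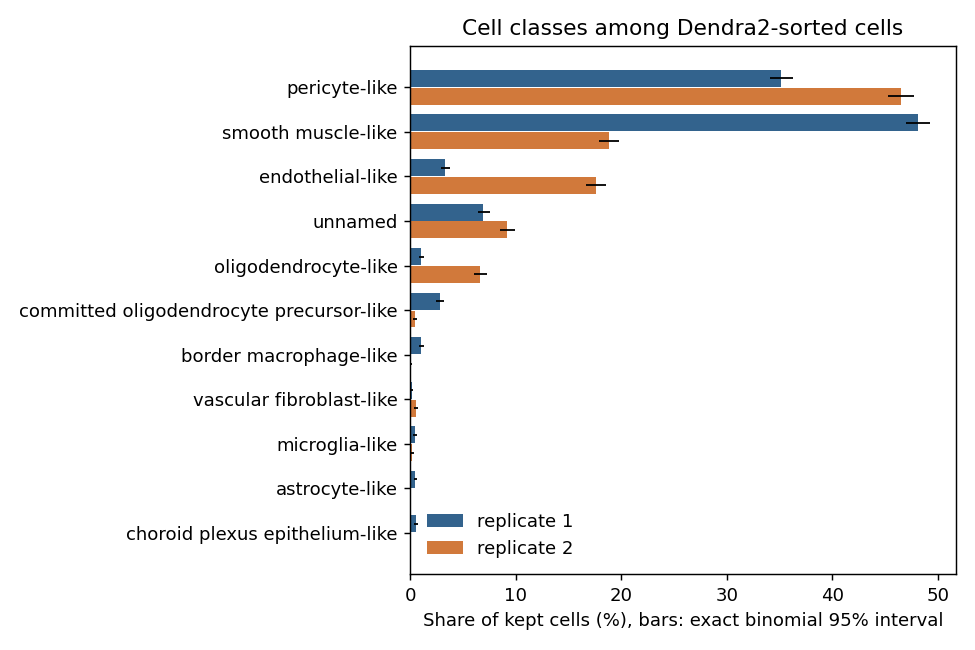
Share of kept cells per class in percent (horizontal axis) for each library, with black lines for exact binomial 95% intervals. Smooth muscle-like cells are at 48.1% of replicate 1 and 18.8% of replicate 2, where endothelial-like cells are at 17.6%.

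Dmp1 transcripts were found mainly in smooth muscle-like cells. Dmp1 (ENSMUSG00000029307, GRCm38 chromosome 5, 104202613 to 104214102, plus strand) reached 24.9 CPM (23.2 to 26.7, 787 UMIs) in smooth muscle-like cells of replicate 1 and 31.5 CPM (26.8 to 36.7, 164 UMIs) in those of replicate 2, a mean of 28.2 ± 4.64. These cells held 94.8% of the 830 and 95.3% of the 172 Dmp1 UMIs of all kept cells. Pericyte-like cells had 0.786 and 0.396 CPM, and endothelial-like cells 0.580 and 1.13 CPM. Oligodendrocyte-like cells had 0.704 CPM in replicate 1 and no UMI in replicate 2, which allows up to 0.565 CPM. The level in smooth muscle-like cells was 31.7 and 27.9 times that of the next of these 4 classes.

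A Dmp1 UMI was present in 449 of 3610 smooth muscle-like cells of replicate 1 (12.4%, 11.4 to 13.6) and in 91 of 1208 of replicate 2 (7.53%, 6.11 to 9.17). In pericyte-like cells, taken as the background, the shares were 0.379% and 0.1%. Median depths were 8606 and 4282 UMIs in smooth muscle-like and 4511 and 2459 in pericyte-like cells. After thinning to 2000 UMIs per cell the expected shares were 3.82% and 4.28% in smooth muscle-like cells, 0.176% and 0.107% in pericyte-like cells, and 0.0314% and 0.118% in endothelial-like cells. Thinning left out 11 and 63 smooth muscle-like, 88 and 798 pericyte-like, and 11 and 145 endothelial-like cells. Among smooth muscle-like clusters of replicate 1, Dmp1 was at 36.8 CPM (33.4 to 40.5) in cluster 2, 27.1 (24.2 to 30.2) in cluster 4, where Cnn1 was highest, and 4.70 (3.33 to 6.45) in cluster 5, where the pericyte marker Rgs5 was at 12842 CPM against 687 CPM in cluster 4.

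In the edgeR quasi-likelihood fit, Dmp1 was 6.15 ± 0.36 (log2, SE) higher in smooth muscle-like cells than in the mean of the other classes (adjusted p = 7.99e-06), and higher in both libraries. That mean includes oligodendrocyte-like cells, with 1 and 0 Dmp1 UMIs, so the size of this value rests partly on the prior count. The same contrast gave -1.53 ± 0.86 for pericyte-like cells (adjusted p = 0.205) and -0.71 ± 0.90 for endothelial-like cells (adjusted p = 0.563), neither past the threshold. For oligodendrocyte-like cells it gave -3.92 ± 1.00 (adjusted p = 0.0102), a fitted value that rests on the prior count because replicate 2 had no UMI. In astrocyte-like cells of replicate 1, 3 of 37 cells held 1 Dmp1 UMI each, or 13 CPM (2.68 to 38.0), and Acta2 was at 1126 CPM there. The 2 astrocyte-like cells of replicate 2 had none, which with 4373 UMIs bounds nothing below 686 CPM. Committed oligodendrocyte precursor-like cells of replicate 1 had 14 Dmp1 UMIs in 5 of 213 cells (5.41 CPM, 2.96 to 9.07), with 7 in a single cell and 4 in another.

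**Figure D2:**
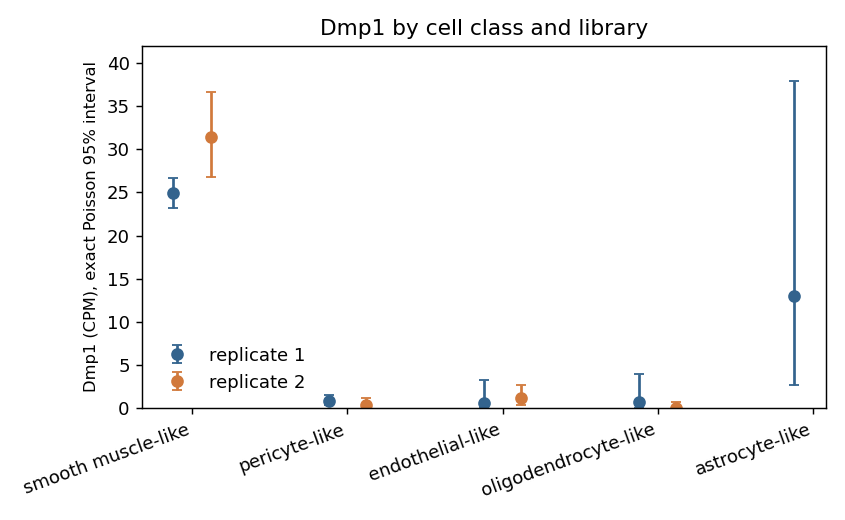
Dmp1 in CPM (vertical axis) in 5 cell classes of each library, with exact Poisson 95% intervals; astrocyte-like cells of replicate 2 are not drawn because there were 2. Smooth muscle-like cells sit at 24.9 and 31.5 CPM, and pericyte-like, endothelial-like and oligodendrocyte-like cells at or below 1.13 CPM.

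The reporter marks mitochondria, so mitochondrial transcripts were compared between the classes. Mitochondrially encoded genes took a median of 10.8% of UMIs in smooth muscle-like cells of replicate 1 and 6.52% in those of replicate 2 (8.65% ± 3.02), above pericyte-like (5.63% and 3.69%), endothelial-like (5.12% and 3.68%) and oligodendrocyte-like cells (8.44% and 5.35%) in each library. Astrocyte-like cells of replicate 1 had 10.1%. These shares exclude cells at 20% or more.

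Smooth muscle-like cells were compared with the equal-weight mean of pericyte-like, endothelial-like and oligodendrocyte-like cells (n = 2 libraries per class). All 13 mitochondrially encoded mRNAs were higher, with a median log2 difference of 0.96, among them mt-Nd4 by 1.15 ± 0.16 and mt-Co1 by 1.08 ± 0.18. Nuclear genes of the respiratory chain were higher too: 27 of 36 of complex I (31 adjusted over the list alone, median 0.67), all 13 of complexes II and III (13 adjusted over the list alone, 0.78), all 15 of complex IV (15 adjusted over the list alone, 0.85) and all 16 of complex V (16 adjusted over the list alone, 0.84). Cox4i2, the oxygen-responsive isoform of a complex IV subunit, was higher by 2.00 ± 0.18, Cox8a by 1.60 ± 0.14 and the ATP synthase inhibitor Atpif1 by 1.79 ± 0.15, although pooled counts of the other cells, in which pericyte-like cells outnumber the rest, had more Cox4i2 than smooth muscle-like cells in replicate 1 (812 against 261 CPM) and replicate 2 (426 against 359 CPM).

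Other metabolic lists lay in the same direction. The tricarboxylic acid (TCA) cycle had 17 of 18 genes higher (18 adjusted over the list alone, median 0.89), led by the mitochondrial isocitrate dehydrogenase Idh2 at 2.33 ± 0.11. Glycolysis and lactate genes had 15 higher and 1 lower of 23 (16 and 1 adjusted over the list alone, 0.68), with the lactate transporter Slc16a7 at 3.80 ± 0.26 and the phosphofructokinase Pfkp at 2.06 ± 0.13. Fatty acid oxidation had 9 of 18 higher (9 adjusted over the list alone, 0.35), among them Acadm by 1.44 ± 0.11. Genes of MICOS, the cristae organising complex, and of mitochondrial import had 10 of 25 higher (10 adjusted over the list alone, 0.34), with Vdac1 at 0.99 ± 0.12. The median of this last list was 0.55 in replicate 1 alone and 0.14 in replicate 2 alone.

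Beyond metabolism, caveolar genes had 10 higher and 2 lower of 12 (10 and 2 adjusted over the list alone, median 1.99), with the coat proteins Cavin1 at 3.45 ± 0.23 and Cavin3 at 3.27 ± 0.22. The reactive astrocyte list had 8 higher and 1 lower of 15 (10 and 1 adjusted over the list alone, 1.34), and its leading members here were Serping1, an inhibitor of complement C1, at 4.07 ± 0.22, and the intermediate filament gene Vim at 3.80 ± 0.18. Immediate-early genes had 12 of 23 higher (12 adjusted over the list alone, 1.19), with Fosl2 at 3.06 ± 0.33 and Nr4a1 at 2.43 ± 0.27. Blood-brain barrier transporters had 18 of 19 lower (18 adjusted over the list alone, -2.84), including the glucose transporter Slc2a1 at -2.79 ± 0.18 and the lipid transporter Mfsd2a at -4.93 ± 0.49. Tight junction genes had 8 lower and 2 higher of 14 (8 and 3 adjusted over the list alone, -1.57), with Jam2 at -2.90 ± 0.26.

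The edgeR fit tested 12778 genes, and of the 11580 counted, 2806 were higher and 1751 lower in smooth muscle-like cells. The named genes were Susd5 (6.60 ± 0.23), Sh3bgr (6.39 ± 0.16), Dpysl3, Kcnab1, Lrrc10b, Npnt, Ramp1, Ntrk3, Olfml2a and Myocd, a coactivator of contractile genes (5.10 ± 0.43), among those higher. Kcnab1, Lrrc10b, Susd5 and Sh3bgr also led smooth muscle-like clusters. Named genes lower in smooth muscle-like cells were Plekhg1 (-5.53 ± 0.32), Gstm7 (-4.47 ± 0.24), Hhip, Dusp26, Tmem125, Zfp536, Ano4, Pde8a, Chd7 and St6galnac3, which had 3 UMIs in smooth muscle-like cells, a CPM ratio of 0.00236 (0.000486 to 0.00691) to the other cells.

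Camera called 12 of 27 lists higher and 2 lower, with adjusted p from 2.19e-07 for barrier transporters and 3.26e-07 for the TCA cycle to 0.0172 for fatty acid oxidation and 0.0288 for tight junctions. None of the 27 was called with an estimated correlation: adjusted p = 0.246 with an estimated correlation for the TCA cycle, 0.453 to 0.485 for the other called lists, and 2 lists had an unadjusted p under 0.05, while fry called 23. Lists not called were fusion and fission (5 higher and 2 lower of 17, 6 and 2 adjusted over the list alone), mitochondrial transport (6 and 3 of 20, 6 and 3 adjusted over the list alone), intercellular mitochondrial transfer (4 and 9 of 27, 4 and 10), mitophagy (5 and 7 of 23, 5 and 7), biogenesis (5 and 0 of 21, 5 and 0), mitochondrial ribosome (18 and 1 of 77, 11 and 1) and mitochondrial stress response (5 and 2 of 19, 4 and 2). Those for astrocyte endfeet (6 and 3 of 11, 6 and 4 adjusted over the list alone), astrocyte-derived vascular ligands (7 and 3 of 13, 7 and 3), endothelial receptors (10 and 9 of 20, 10 and 9), antioxidants (8 and 6 of 25, 9 and 6), nuclear RNA (3 and 0 of 5, 3 and 0) and the SIBLING family of Dmp1 (1 and 1 of 3, 2 and 1) were not called either. The SIBLING list was fixed with Dmp1 and some genes outside that family in it, and its 1 higher gene was Dmp1 itself. The median and the mean differed in sign for fusion and fission (-0.01 and 0.12), mitophagy (0.02 and -0.17) and endothelial receptors (0.32 and -0.26). The camera direction followed the mean for fusion and fission and for mitophagy, and the median for the receptors.

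**Figure D3:**
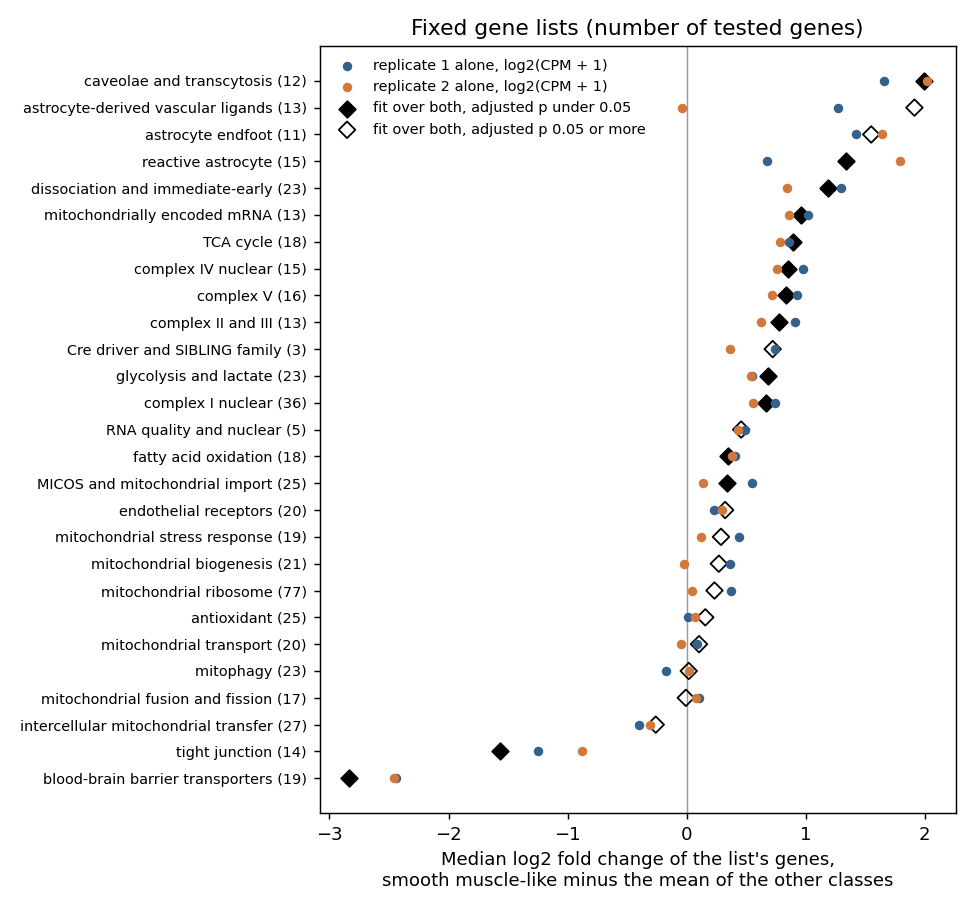
Median log2 fold change of each fixed list (horizontal axis), smooth muscle-like cells minus the mean of the other classes; diamonds are the edgeR fit, filled where the camera adjusted p was under 0.05, and dots are each library alone. The mitochondrially encoded list lies at 0.96 and the barrier transporters at -2.84, and these 2 lists lie on the same side of 0 in both libraries.

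Endothelial-like cells, which form the barrier the series title refers to, were then compared with smooth muscle-like cells. All 19 barrier transporters were higher in endothelial-like cells (19 adjusted over the list alone, median 7.88), with Slc2a1 at 6.27 ± 0.23 and Slc6a6, the taurine transporter, at 5.52 ± 0.22. Tight junction genes had 12 higher and 1 lower of 14 (12 and 1 adjusted over the list alone, 3.19), with Jam2 at 7.26 ± 0.27 and Lsr at 7.46 ± 0.30. Endothelial receptors had 11 higher and 1 lower of 20 (11 and 3 adjusted over the list alone, 0.89), with the VEGF receptor Kdr at 8.92 ± 0.33 and Acvrl1 at 5.77 ± 0.31.

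Genes fixed as candidates for intercellular mitochondrial transfer had 12 higher and 2 lower of 27 in endothelial-like cells (14 and 2 adjusted over the list alone, median 0.50). Gja1 (connexin 43, a gap junction protein) was higher by 7.36 ± 0.74 (66.7 and 67.4 CPM against 0.190 and 0.959), Exoc6 by 3.04 ± 0.27, Myo10 by 2.05 ± 0.15 and Rab11a by 1.64 ± 0.15. The respiratory chain lists lay in the opposite direction: 13 of 13 mitochondrially encoded mRNAs (13 adjusted over the list alone, -1.28), 25 of 36 complex I genes (27, -0.81), 13 of 13 of complexes II and III (13, -0.79), 12 of 15 of complex IV (12, -1.07) and 14 of 16 of complex V (15, -0.85) were lower in endothelial-like cells. Lower too were 17 of 18 TCA cycle genes (17 adjusted over the list alone, -1.08), with Idh2 at -2.70 ± 0.17, 11 of 25 MICOS and import genes (11, -0.55), and 12 of 23 glycolysis genes against 1 higher (12 and 2, -0.62), with Ldhb at -2.45 ± 0.18. The mitochondrial ribosome had 15 lower and 1 higher of 77 (8 and 1 adjusted over the list alone, -0.26), with Mrps6 at -1.77 ± 0.29. The median of this list was -0.40 in replicate 1 alone and -0.07 in replicate 2 alone. Dmp1 was at -5.15 ± 0.51 (edgeR adjusted p = 0.000102).

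Of the 11580 genes counted, 1984 were higher and 2440 lower in endothelial-like cells. The named higher genes had 1 to 8 UMIs in smooth muscle-like cells. They were Tnfsf10, with a CPM ratio of 2629 (469 to 104077), St6galnac3, with 1219 (415 to 5927), Rab11fip1, with 503 (254 to 1171), Gbp9, Myct1, Mfng, Sigirr, Unc45b, Thsd1 and Rnf125. The named lower genes were Lrrc10b (-5.80 ± 0.26), Ramp1, a subunit of the CGRP receptor (-5.59 ± 0.46), Kcnab1 (-5.10 ± 0.30), Nkx6-1, Ctnna3, Lox, Sh3bgr, Smim5, Susd5 and Tesc.

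Camera called 4 lists higher and 9 lower, with adjusted p from 7.8e-16 for barrier transporters to 0.0407 for the mitochondrial ribosome. None of the 27 was called with an estimated correlation: adjusted p = 0.406 with an estimated correlation for barrier transporters, tight junctions and the TCA cycle, 0.474 to 0.826 for the other called lists, and 3 lists had an unadjusted p under 0.05, while fry called 20. Not called were fusion and fission (1 higher and 3 lower of 17, 1 and 3 adjusted over the list alone), mitochondrial transport (1 and 5 of 20, 0 and 4), mitophagy (4 and 3 of 23, 4 and 3), biogenesis (1 and 4 of 21, 1 and 4), fatty acid oxidation (4 and 6 of 18, 6 and 8), stress response (1 and 8 of 19, 1 and 10), antioxidants (5 and 5 of 25, 5 and 5), caveolae (3 and 6 of 12, 3 and 6), endfeet (2 and 5 of 11, 2 and 5), vascular ligands (4 and 7 of 13, 4 and 7), immediate-early genes (3 and 4 of 23, 0 and 1), reactive astrocytes (3 and 4 of 15, 3 and 4), nuclear RNA (0 and 2 of 5, 0 and 3) and the SIBLING family (0 and 1 of 3, 0 and 1). In the SIBLING list the 1 lower gene was Dmp1 itself. The antioxidant list had a median of -0.03 and a mean of 0.02.

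Within the smooth muscle-like class, cells with a Dmp1 UMI were compared with cells matched for depth (449 and 1347 cells in replicate 1, medians 9578 and 9579 UMIs, 91 and 273 in replicate 2, medians 4862 and 4850). Cells with a Dmp1 UMI had higher Pdgfc, a platelet-derived growth factor gene, by 1.18 ± 0.17, higher Inhba, which encodes an activin subunit, by 1.14 ± 0.15, and higher Trim2, Susd5, Wwp2, Phlda3, Olfml2a, Ntrk3 and Klhl23. They had lower Foxd1, a forkhead transcription factor gene (-0.72 ± 0.13), and lower Enpep (-0.69 ± 0.14), Ggt5, Adap2, Slco3a1, Inpp4b, Gfra2, Ndufa4l2 and Pid1. Matched within the cluster, Foxd1 kept its call, but every other of these lower genes lost it. Their edgeR adjusted p there was lowest for Inpp4b (0.0896) and was 0.794 for Enpep. Wwp2, Olfml2a and Ntrk3 among the higher genes lost the call too (edgeR adjusted p = 0.0896, 0.0866 and 0.391). Clustering features and markers, chosen after their values were seen, included Mgp (1.10 ± 0.10), S100a6 (1.03 ± 0.14) and Anxa1 (0.94 ± 0.14) among the higher genes, and Car4 (-1.97 ± 0.14), the pericyte marker Vtn (-1.69 ± 0.11), Ogn (-1.29 ± 0.15), Casq2 (-1.23 ± 0.13) and Rgs5 (-0.90 ± 0.09) among the lower. The SE of this test do not show the spread between the libraries. Replicates 1 and 2 alone gave 0.88 and 2.91 for Pdgfc, and -1.49 and -3.22 for Car4 (log2).

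The edgeR test called 44 genes higher and 82 lower of 10284, 115 of the 126 with the same sign in both libraries, and 72 of them were features or markers. None of the tested lists was called by camera (lowest adjusted p = 0.605, adjusted p = 0.992 with an estimated correlation). The 13 mitochondrially encoded mRNAs had a median of 0.03 and none was called. Immediate-early genes had 2 higher and 3 lower of 23 (9 adjusted over the list alone), reactive astrocyte genes 1 and 2 of 14 (6 adjusted over the list alone) and vascular ligands 0 and 2 of 11 (5 adjusted over the list alone). Intercellular transfer, antioxidant and nuclear RNA lists had 1 lower gene each (1, 2 and 2 adjusted over the list alone), complex IV had 0 (1 adjusted over the list alone), and the other lists had 0 by either count. The median and the camera direction differed in sign for complexes II and III (-0.01), complex V (-0.02), the TCA cycle (0.03) and reactive astrocytes (0.05). List members called were Egr2, Nfkbia and Vim, which were higher, and Eps8, Ptn, Igfbp2, Mt1, Fosb, Hspa1a, Hspa1b, Cp, Iigp1 and Meg3, which were lower, also chosen after their values were seen. Of the cells with a Dmp1 UMI in replicate 1, 6.46% were in cluster 5, against 25.4% of matched cells; matched within clusters, 25 genes were higher and 20 lower, and 42 genes were called in both matchings. DESeq2 called 6 and 8 genes, and without the replicate block no gene was called by edgeR (59 at an unadjusted p under 0.05).

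**Figure D4:**
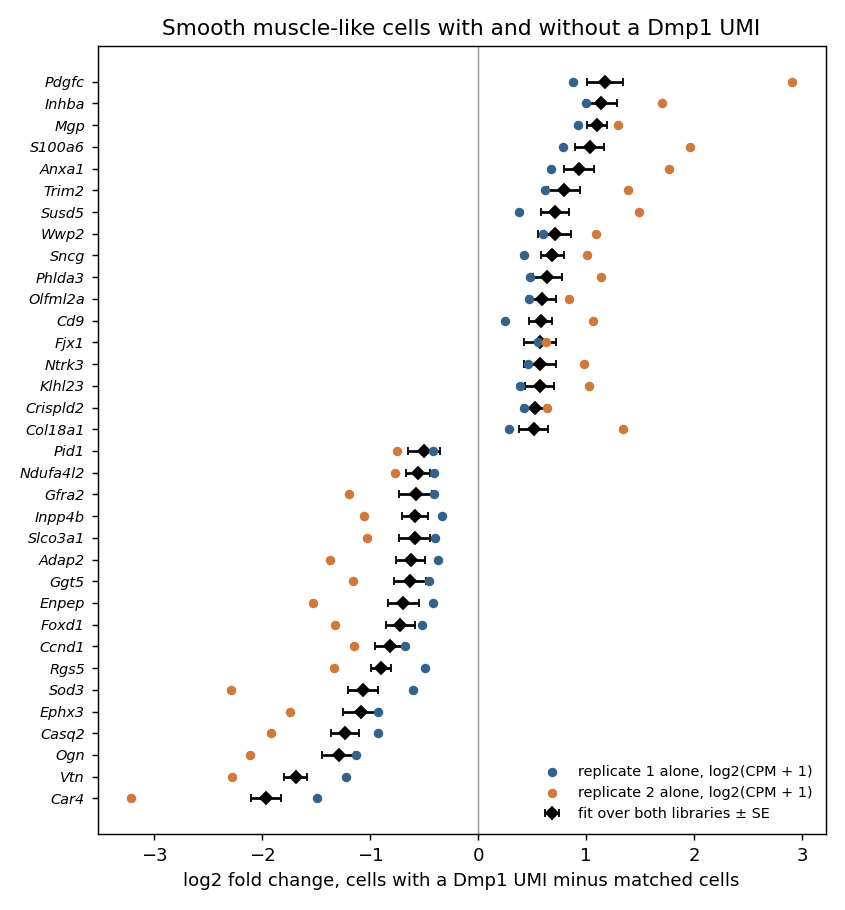
Log2 fold change (horizontal axis) of named genes between smooth muscle-like cells with a Dmp1 UMI and depth-matched cells without one; diamonds are the edgeR fit with SE, and dots each library alone. Inhba lies at 1.14 and Car4 at -1.97, and each gene drawn has the same sign in both libraries.

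Endothelial-like and astrocyte-like cells could be set side by side only in replicate 1, with 250 and 37 cells and no replicate check. Barrier transporters were higher in endothelial-like cells for 19 of 19 genes (median log2 ratio 3.11, percentile 100 among random lists), tight junction genes for 10 of 12 (3.39, percentile 100) and endothelial receptors for 15 of 19 (2.02, percentile 100). Slc2a1 was at 2320 CPM (2249 to 2394) against 260.0 (198 to 335), and the efflux pump gene Abcb1a at 893 (849 to 939) against 4.33 (0.110 to 24.1). Ocln was at 379 CPM (350.2 to 409), against no UMI in astrocyte-like cells (which allows up to 13 CPM). Caveolar (1.92, percentile 99.9), immediate-early (1.73, percentile 100) and reactive astrocyte genes (2.68, percentile 100) were also higher in endothelial-like cells.

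Astrocyte endfoot genes had a median of -4.72 and astrocyte-derived vascular ligands of -2.92, both at percentile 0 and with 2 of 14 genes higher in endothelial-like cells. Aqp4, the endfoot water channel, was at 1009 CPM (884 to 1148) in astrocyte-like cells and had no UMI in endothelial-like cells (which allows up to 1.74 CPM), and Gja1 was at 1867 (1695 to 2052) against 66.7 (55.1 to 80.1). Vegfa was at 498 CPM (411 to 598) against 2.32 (0.632 to 5.94). Glycolysis (-0.95, percentile 0.34) and TCA cycle genes (-0.67, percentile 0.92) lay on the astrocyte side. The mitochondrially encoded mRNAs had a median of -0.67, with 3 of 13 higher in endothelial-like cells. Their percentile of 61.1 decides nothing, since random lists matched at the top of the expression range can draw these same genes. Nuclear genes of complexes I to V lay between percentiles 5.06 and 13.6. Intercellular transfer genes lay at 77.7 (median 0.34), mitophagy at 90.6 (0.53) and mitochondrial transport at 45.7 (0.08). Cd38, an enzyme studied in mitochondrial transfer, was at 165 CPM (117 to 226) in astrocyte-like and 56.8 (46.1 to 69.3) in endothelial-like cells, and smooth muscle-like cells had no Cd38 UMI (which allows up to 0.0950 CPM).

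The libraries were compared within each class as the only replicates. Across genes, log2 CPM correlated with Pearson's r of 0.927 in endothelial-like, 0.923 in oligodendrocyte-like, 0.905 in pericyte-like and 0.883 in smooth muscle-like cells (Spearman's rho 0.927, 0.922, 0.921 and 0.879), where genes are not independent replicates. Immediate-early and heat-shock genes stood apart: all 23 of the list were higher in replicate 2 in all 4 classes, with median log2 ratios of 3.72, 5.05, 5.67 and 4.50. In smooth muscle-like cells Fos was at 36.7 CPM in replicate 1 and 2883 in replicate 2, and Hspa1a at 62.9 and 1426. In endothelial-like cells Fosb, Fos, Nr4a1, Hspa1b and Egr3 had the largest ratios toward replicate 2, and Cxcl10, Plpp3, Ifit1, Ttc14 and Iigp1 toward replicate 1, with Cxcl10 at 121 against 3.38 CPM. In smooth muscle-like cells these were Cxcl1, Fosb, Nr4a2, Atf3 and Mt2, and Eln, Igfbp4, S100a6, Cnn1 and Col3a1. In pericyte-like cells Fos, Fosb, Atf3, Rasd1 and Ccl2 had the largest ratios toward replicate 2. Toward replicate 1 these were Acta2 (1469 against 91.9 CPM), Tagln (1068 against 91.4 CPM), Olfr558, Nrip2 and Ccnd1. Acta2 and Tagln were highest in pericyte-like cluster 6, which had 645 cells in replicate 1 and 17 in replicate 2. In replicate 1, Acta2 was at 4148 CPM in cluster 6, against 282 and 184 CPM in clusters 0 and 1. The class thus carried smooth muscle transcripts mainly through cluster 6 of replicate 1. In oligodendrocyte-like cells Fos, Junb, Fosb, Klf4 and Egr1 had the largest ratios toward replicate 2, and Marcks, Hist1h1c, Ctps and Hcn2 were among the largest toward replicate 1.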

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

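All tests of this part were chosen after the result was seen, except the Acta2 level of the 8 cells named below.

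Dmp1 UMIs also appeared in data that entered no comparison. Barcodes left out by the filters held 55 Dmp1 UMIs in replicate 1 (13.1 CPM, 9.86 to 17.0) and 4 in replicate 2 (6.16 CPM, 1.68 to 15.8). In replicate 1, called doublets were at 12.9 CPM and barcodes over the mitochondrial limit at 14.9 CPM. Unnamed cluster 9 held 14 Dmp1 UMIs in replicate 1 (13.7 CPM, 7.47 to 22.9) and none among 365 cells of replicate 2 (which allows up to 3.06 CPM). That cluster combined Rgs5 at 17233 CPM with Acta2 at 4340 CPM in replicate 1 and was left unnamed because it had markers of both pericytes and smooth muscle.

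Dmp1 was concentrated in smooth muscle-like cells in both libraries, and neither depth nor free RNA accounts for this: Dmp1 CPM was at least 27.9 times that of the next of the 4 tested classes, and at least 31.7 times that of pericyte-like cells. The few Dmp1 UMIs of pericyte-like, endothelial-like and oligodendrocyte-like cells may in replicate 2 be free RNA from smooth muscle-like cells or doublets with them. There the 8 UMIs were no more than the 9.26 that their Acta2 would bring (exact Poisson p = 0.705). This cannot tell free RNA from doublets, which bring Acta2 and Dmp1 at the same ratio. Endothelial-like cells held 5 of the 8, in 3 cells. With the highest 6% of doublet scores left out, their Dmp1 in replicate 2 went from 1.13 to 0.226 CPM, while pericyte-like cells went from 0.396 to 0.462 CPM. Whether free RNA was the source in replicate 1 could not be decided. Pericyte-like cells held Acta2 at 1469 CPM there, against 234 CPM in oligodendrocyte-like cells, and not all of it need be free RNA. An expectation that counts all of it could hardly be exceeded. In astrocyte-like and committed oligodendrocyte precursor-like cells of replicate 1, 17 Dmp1 UMIs exceeded the 4.41 expected from their Acta2 (exact Poisson p = 4.11e-06). The 242 such cells without a Dmp1 UMI had Acta2 at 5.10% of the smooth muscle-like level, and 53 of them were over 25%. The 8 cells holding the Dmp1 UMIs had Acta2 at 33.4% of that level. Of the 17 UMIs, 12 were in 3 of these cells, each with Acta2 at or over 25% of that level. The Poisson test takes UMIs as independent, so its p-value overstates the strength of the excess. Doublets with a smooth muscle-like cell are a candidate explanation for part of these cells, but not for the 4 with 0 or 1 Acta2 UMI. Those were picked for an exact Poisson upper bound of Acta2 under 10% of that level, and the highest bound was 3.30%. Over all 194 such cells with Acta2 under 25% of that level, 5 Dmp1 UMIs cannot be told apart from free RNA because they are too few: at the level of the other classes 1.89 would be found (exact Poisson p = 0.0430 with that level taken as known, exact binomial p = 0.0700 with the counting error of its 12 UMIs), the lower expectation from their Acta2 (0.898, exact Poisson p = 0.00232) holds for cells chosen by low Acta2, and no biological explanation was tested.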

How the results depend on the processing

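The alternatives for cell shares, Dmp1 by class and mitochondrial shares were planned, except the highest 6% of doublet scores left out and each library clustered alone. All alternatives for the class tests and the matched test were added after the data were seen, and the changes of settings planned for the astrocyte tests were not run because those tests were not. Of the alternative values of the main results, 212 were counted as near the value or count reported, 27 as moved, and none as reversed. For shares and CPM, near meant within the SD of the 2 libraries, which each replicate alone meets by arithmetic. That SD exceeded the mean for astrocyte-like (0.262% ± 0.326) and oligodendrocyte-like shares (3.83% ± 3.92), so the label says little there. For counts of genes and lists, near meant within 1.5-fold. Shares, CPM and counts cannot reverse. Unless stated, the cause of a move was not tested. As means of the libraries, shares of the classes stayed within the spread between them: smooth muscle-like cells at 30.7% to 36.2%, pericyte-like at 37.2% to 44.6% and endothelial-like at 9.20% to 11.7%. In replicate 2 alone, the smooth muscle-like share of 18.8%, above the endothelial-like 17.6%, fell below the endothelial-like share with no filter on the mitochondrial share (13.9% against 17.4%), at Leiden resolution 2 (12.2% against 17.7%), with the highest 6% of doublet scores left out (13.2% against 18.6%) and with each library clustered alone (13.3% against 14.5%). As the mean of the libraries, Dmp1 in smooth muscle-like cells stayed between 27.3 and 34.7 CPM, the highest at Leiden resolution 2. Single libraries ranged more widely. Replicate 1 was lowest at 21.2 CPM with the highest 6% of doublet scores left out, and replicate 2 highest at 44.4 CPM at Leiden resolution 2. The thinned share of smooth muscle-like cells with a Dmp1 UMI, 4.05% as the mean of the libraries, was 4.49% with no filter on the mitochondrial share, 5.01% at Leiden resolution 2, 4.63% with the highest 6% of doublet scores left out, 4.65% with each library clustered alone and, by construction, 2.22% when thinned to 1000 UMIs.

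In smooth muscle-like cells against the other classes, Dmp1 was higher by 5.82 to 8.10 across the fits; each library alone gave 4.10 to 4.76 on the log2(CPM + 1) scale, which lowers the change of genes near 0. Lists lower there went from 2 to 1 with no filter on the mitochondrial share, at Leiden resolution 0.5 and with the highest 6% of doublet scores left out. With no replicate block, genes lower in that contrast went from 1751 to 1080, and lists lower in endothelial-like against smooth muscle-like cells from 9 to 5. With an estimated correlation, 0 lists were called higher and 0 lower in either contrast; fry, which does not compare a list with other genes, called 16 lower in endothelial-like against smooth muscle-like cells and 21 higher in smooth muscle-like cells. DESeq2 size factors moved the share of higher calls from 44.8% to 49.1% and from 61.6% to 57.2%.

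In the matched test, with 44 genes higher and 82 lower, matching within the cluster called 25 and 20, 1 matched cell 25 and 48, which has fewer cells, DESeq2 6 and 8 (its adjusted p was missing for 5583 genes) and no replicate block 0 and 0. Among named genes, 1022 of 1022 alternative values kept direction and call for endothelial-like against smooth muscle-like cells, 913 of 924 for smooth muscle-like cells against the other classes, and 124 of 216 in the matched test; the others lost the call, and none reversed. Depth limits replicate 2, with 26218090 UMIs against 59026190.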

Other observations

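The hypothesis tests of this part were chosen after the result was seen, except the test of the mitochondrial limit, and the genes of the next paragraph were chosen after their values were seen.

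Single members of lists that were not called passed the edgeR threshold in smooth muscle-like cells against the mean of pericyte-like, endothelial-like and oligodendrocyte-like cells. The coactivators Ppargc1a and Ppargc1b, which drive mitochondrial biogenesis, were higher in smooth muscle-like cells by 2.70 and 2.81 (log2), and the nuclear receptor Esrra by 1.34. The stress-responsive transcription factor Atf5 was higher by 2.32. The mitophagy receptors Bnip3 and Bnip3l were lower, at -1.43 and -1.37, in a mitophagy list with 5 genes higher and 7 lower of 23. Mfn2, a mitofusin, was higher in smooth muscle-like cells by 1.55 and Mfn1 lower, at -0.65. Among antioxidant genes, smooth muscle-like cells had higher Prdx5 (1.45) and Sod2 (0.79), and lower Hmox1 (-1.51) and Cat (-1.47).

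Smaller populations stood beside the vessel cells. Unnamed cluster 3, with 179 cells in replicate 1 and 9 in replicate 2, was led by Ccl19, Col3a1 and Colec11. Cluster 11, with 35 and 135 cells, had markers of both endothelial cells and pericytes, with Cldn5 at 3778 and 3368 CPM and Vtn at 9326 and 8292 CPM. Cluster 18, with 14 and 82 cells, combined Hbb-bs at 141928 and 188551 CPM with Cldn5 at 3716 and 2729 CPM. Cluster 10, with 41 cells and 1 cell, was led by neuronal genes such as Snap25 and Gad1. None of these clusters held a Dmp1 UMI.

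The respiratory chain and mitochondrially encoded lists that camera called higher in smooth muscle-like cells were not called at adjusted p = 0.453 to 0.484 with an estimated correlation. For the medians of these lists, scaling of the libraries is argued against, since a factor shared by all genes of a library moves every gene alike, while the lowest of the 5 list medians lay 0.65 (log2) above the median of all tested genes. Damaged cells that keep mitochondrial RNA are argued against as the cause for the 4 nuclear-encoded lists, which were higher too, with a lowest median of 0.56 in either library. Whether such cells added to the mitochondrially encoded list could not be decided, since both rises can occur together. The limit on the mitochondrial share is argued against, since without it the median of the mitochondrially encoded list moved by 0.0118. No biological explanation was tested.

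Immediate-early and heat-shock genes were higher in replicate 2. A different mix of classes is argued against, since the lowest within-class median log2 ratio was 3.72. Free RNA in replicate 2 as the whole cause is argued against, since the ratio of Hspa1a to Fos differed 11.2-fold between pericyte-like cells (0.782, 0.772 to 0.793) and oligodendrocyte-like cells (0.0697, 0.0652 to 0.0744). A different handling of the cells may be the cause, but handling and replicate cannot be told apart, since the labels used here record 0 handling steps that differ between the libraries. No biological explanation was tested.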
